A study of Homo sapiens with 21 samples.

How the data were processed

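The series holds 21 arrays of HMLE cells, with 3 arrays in each of 7 groups (pWZL, Twist, Snail, Gsc, TGFb, shGFP and shEcad). Per the labels' protocols, cells were transduced with retroviruses, selected with blasticidin and grown before total RNA was extracted, labelled with biotin and hybridised to Affymetrix arrays. The deposited table gives linear intensity values made by the authors with RMA, per the submitters' processing notes; the version of RMA is not given in the sources used here. RMA subtracts background, makes the distributions of the arrays alike and summarises the probes of each probe set, so that a shift in total RNA would not be seen and differences of low values are compressed. A description label mentions drug treatments that the titles and the design text do not, and groups were taken from the titles.

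The values were log2-transformed, since the table held a linear scale where a log2 scale had been assumed when the tests were chosen; no other normalization was applied. The table holds 16383 probe sets and ends at probe set 217013_at, and later probe sets of the array were not analysed here. Of these, 14542 had 1 gene symbol in the platform annotation, 455 had several and 1386 were not listed with a gene. The symbols of 14531 probe sets were matched by Entrez ID to a RefSeq gene table of assembly GRCh38.p14, and 0 symbols changed. Each of the 8743 genes was represented by the probe set with the highest mean over all arrays; 3505 genes had more than 1 probe set. Probe sets with several symbols or none entered no comparison between groups of genes. No coordinates were used.

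All 21 arrays were fitted together with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with the group as the only factor, which left 14 residual degrees of freedom and a prior of 5.70. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 within a comparison and a change of at least 2-fold; "rose" and "fell" without a fold mean an adjusted p under 0.05. Twist, Snail, Gsc and TGFb were compared with pWZL, and shEcad with shGFP, following the vector names, because the labels do not state which control belongs to which group. The number of arrays limits the precision; the median SE of a difference was 0.0960. The median log2 difference over all genes lay between -0.0146 and 0.024 in the 5 comparisons. Genes shared by all 5 comparisons, the 6 direct contrasts among Twist, Snail, Gsc and TGFb, the 4 differences from the hairpin effect and shGFP against pWZL came from the same fit. No label gives a batch or a scan date.

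For 32 gene lists (cell-cell junctions, epithelial regulators and apical proteins, keratins, cornified envelope and squamous genes, hemidesmosome and laminin genes, mesenchymal markers, EMT transcription factors, collagens, contractile genes, TGF-beta ligands and receptors, TGF-beta target genes, Wnt genes, matrix proteases, EGF receptor family genes, PDGF and FGF genes, inflammatory cytokines, interferon-stimulated genes, antigen presentation, cell cycle, p53 target genes, hypoxia and glycolysis, cholesterol synthesis, unfolded protein response, oxidative phosphorylation, ribosomal proteins, mammary stem cell genes, and markers of luminal cells, basal cells, fibroblasts, endothelial cells, leukocytes and adipocytes), limma's camera was run with a preset inter-gene correlation of 0.01, 2-sided, and adjusted over all 160 tests of 32 lists in 5 comparisons. Camera with an estimated correlation and fry were run beside it. Counts of list members use the adjusted p over all genes, and counts adjusted over the list alone are given beside them. The list tests for shGFP against pWZL, the direct contrasts and the differences from the hairpin effect were added later and adjusted among themselves.

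The lists, the alternatives and the rule for naming genes were fixed before the data were examined. The rule named the targeted or introduced gene, the 10 largest rises and 10 largest falls among called genes whose 3 arrays all lay on a single side of the 3 control arrays, a fixed set of EMT genes, the 4 members of each list with the largest change, the 15 shared genes per direction with the largest smallest change, and the 3 largest changes per direction of each other contrast. KCNJ15, IGFBP2, DST with its probe sets and MPPE1 were chosen after their values were seen.

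The procedure was tested on simulated data. In a simulated Twist comparison of 8743 genes with 50 changed genes per size, changes of 1.5-, 2-, 3- and 4-fold were found in 94%, 100%, 100% and 100% of cases at any fold, and in 0%, 28%, 100% and 100% at the 2-fold minimum. False calls numbered 10 at any fold and 0 at the 2-fold minimum. Shared controls were examined by simulating unchanged groups against the same control spread. Alternatives covered a second quantile normalization, centring on medians, a filter on the dimmest 30% of genes, means of probe sets, leaving out probe sets ending in _x_at, separate fits, the replicate number as a block, array weights, another eBayes prior, an adjusted p under 0.01, 1.5-fold and no minimum fold, the other or both control vectors, and each array left out in turn. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.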

Results

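Gene expression was measured on 21 Affymetrix arrays of HMLE cells, human mammary epithelial cells immortalized with the SV40 early region and telomerase. The cells had been transduced with retroviral vectors and fell into 7 groups of 3 arrays each, which the series describes as biologic replicates. The vector control pWZL was set against cells given Twist, Snail, Gsc (Goosecoid) or TGFb (transforming growth factor beta), all inducers of the epithelial-mesenchymal transition (EMT). Cells with a short hairpin against E-cadherin (shEcad) were set against cells with a hairpin against GFP (shGFP). The study asked what expression changes these 5 ways of inducing EMT bring about. The log2 medians of the arrays lay between 6.30 and 6.40, and correlations across probe sets were 0.995 to 0.998 within groups and 0.928 to 0.990 between groups. Probe sets are not independent replicates. Differences are log2 fold changes ± SE from the limma fit with n = 3 arrays per group unless stated otherwise, and 8743 genes were tested. The SE and the adjusted p of a gene measure the spread among the arrays of a group. A low adjusted p does not tell the effect of an inducer from another difference between the groups of cells.

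Twist raised genes of the extracellular matrix and lowered epithelial junction genes. The largest rise was that of DCN, which encodes the proteoglycan decorin, by 8.07 ± 0.10 (n = 3 against 3). The fibrillar collagen genes COL1A2 and COL3A1 rose by 7.62 ± 0.07 and 7.39 ± 0.12, and NID1, which encodes the basement membrane protein nidogen, rose by 6.77 ± 0.09. CDH1, the gene of E-cadherin (probe set 201131_s_at), fell by 2.91 ± 0.09, and EPCAM, an epithelial adhesion molecule (201839_s_at), fell by 2.51 ± 0.12. The cytokine gene IL1A fell by 4.64 ± 0.12, the most of all, followed by UCHL1, FGFR3, SAA1 and KLK10, which fell by 4.51 ± 0.13, 4.26 ± 0.16, 4.17 ± 0.11 and 4.04 ± 0.12. Among the named EMT genes, ZEB1, a repressor of CDH1, rose by 5.63 ± 0.10, the intermediate filament gene VIM by 1.45 ± 0.06, and CDH2, the gene of N-cadherin, by 1.44 ± 0.09. TWIST1, the introduced gene, was higher by 1.03 ± 0.11, although whether its probe set lies within the introduced sequence is not known here, and outside it the probe set would not measure the transgene. The rise was not particular to these cells, since TWIST1 also rose by 1.61 with Snail, 0.93 with Gsc, 1.305 with TGFb and 3.12 with shEcad.

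Of 24 measured cell-cell junction genes, 17 fell and 0 rose with Twist (17 and 0 adjusted over the list alone), with a median of -1.49 (camera adjusted p = 2.79e-11). They included the coxsackievirus receptor gene CXADR, which fell by 3.46, and the plakophilin gene PKP2, which fell by 3.13. Of 34 mesenchymal markers, 30 rose and 1 fell (30 and 1 adjusted over the list alone; median 2.26, adjusted p = 1.55e-25), and 10 of 15 collagens rose (10 adjusted over the list alone; median 1.69, adjusted p = 4.81e-10). In all, 390 genes were at least 2-fold higher and 278 at least 2-fold lower than in pWZL (668 together). In the 20 genes with the largest rises and falls, the highest adjusted p was 9.13e-13 and the 3 Twist arrays lay on a single side of the 3 pWZL arrays, as the rule for naming genes required. The pWZL level of 6 of the 10 largest rises, and the Twist level of 1 of the 10 largest falls (CXADR), lay in the lowest 30% of all values, where the size of a fold depends on the background of the arrays. Against shGFP in place of pWZL, 418 genes were higher and 528 lower, so that lower genes outnumbered higher ones, and UCHL1 fell by 1.97, KLK10 fell by 7.37, CDH2 rose by 3.02 and TWIST1 by 2.57.

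Snail raised matrix genes and lowered epithelial genes. COL3A1 rose by 7.79 ± 0.12, DCN by 7.72 ± 0.10, and POSTN, which encodes the matrix protein periostin, by 7.57 ± 0.09 (n = 3 against 3). EPCAM fell the most, by 6.05 ± 0.12, and CDH1 fell by 3.65 ± 0.09. IL1A fell by 5.32 ± 0.12, TPD52 by 4.83 ± 0.08 and SCNN1A, an epithelial sodium channel subunit gene, by 3.95 ± 0.14. ZEB1 rose by 4.74 ± 0.10, VIM by 1.37 ± 0.06, CDH2 by 1.66 ± 0.09 and TWIST1 by 1.61 ± 0.11. SNAI1, the introduced gene, was not analysed here because no single-gene probe set in the table carried its name, while its relative SNAI2 fell by 0.72 ± 0.06.

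Of the junction genes, 21 of 24 fell and 0 rose with Snail (21 and 0 adjusted over the list alone; median -1.92, adjusted p = 3.97e-14). In the test of Twist against Snail, junction genes were higher with Twist, with 6 of 24 higher and 0 lower (median 0.26, adjusted p = 0.000311, with an estimated correlation adjusted p = 0.0168). Of 16 epithelial regulators and apical proteins, 14 fell (14 adjusted over the list alone; median -1.48, adjusted p = 1.3e-11), among them FXYD3 and SPINT1, which fell by 3.76 and 3.43; in shGFP against pWZL 13 were higher and 0 lower (median 0.83). Mesenchymal markers rose in 29 of 34 cases and fell in 1 (30 and 1 adjusted over the list alone; median 1.66, adjusted p = 6.98e-23). At least 2-fold, 358 genes were higher and 325 lower (683 together), and the highest adjusted p in the 20 genes with the largest rises and falls was 7.47e-14. The pWZL level of 5 of the 10 largest rises and the Snail level of 1 of the 10 largest falls (SLPI) lay in the lowest 30% of values. Against shGFP in place of pWZL, 406 genes were higher and 559 lower, so that lower genes outnumbered higher ones, and CDH2 rose by 3.23, TWIST1 rose by 3.16 and SNAI2 fell by 0.27.

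Gsc changed the most genes of the 5 comparisons. DCN rose by 8.74 ± 0.10, COL3A1 by 8.46 ± 0.12, LUM, the gene of lumican, by 7.57 ± 0.14, and MGP, the matrix Gla protein gene, by 7.54 ± 0.16 (n = 3 against 3). SCG2, which encodes a secretory granule protein, rose by 7.21 ± 0.11 and the nuclear receptor gene NR2F1 by 7.16 ± 0.11. CDH1 fell from a log2 level of 11.65 ± 0.12 (SD, n = 3) in pWZL to 4.66 ± 0.08 (SD, n = 3). FGFBP1 fell by 7.28 ± 0.08, EPCAM by 6.73 ± 0.12, KRT5, a basal keratin gene, by 6.53 ± 0.10, TGFBI by 6.37 ± 0.14 and CDH3, the gene of P-cadherin, by 6.18 ± 0.14. ZEB2 rose by 3.17 ± 0.12 and ZEB1 by 2.74 ± 0.10, and CDH2 and VIM rose by 2.93 ± 0.09 and 1.48 ± 0.06. GSC itself was not analysed here, since no single-gene probe set in the table carried its name.

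With Gsc, 18 of 24 junction genes fell and 1 rose (20 and 1 adjusted over the list alone; median -0.90, adjusted p = 9.59e-09), and 29 of 34 mesenchymal markers rose and 2 fell (30 and 2 adjusted over the list alone; median 1.55, adjusted p = 3.1e-16). Interferon-stimulated genes rose in 20 of 26 cases and fell in 0 (21 and 0 adjusted over the list alone; median 0.91, adjusted p = 9.04e-09), led by IFI44L at 4.16, IFITM1 at 3.40, IFI44 at 2.66 and IFIT1 at 2.58. Of 23 genes of hypoxia and glycolysis, 19 fell and 2 rose (19 and 2 adjusted over the list alone; median -0.60, adjusted p = 7.87e-06), and NDRG1 and VEGFA fell by 3.44 and 2.33. In all, 607 genes were at least 2-fold higher and 476 lower (1083 together), with a highest adjusted p of 1.4e-18 in the 20 genes with the largest rises and falls. The pWZL level of 8 of the 10 largest rises and the Gsc level of 3 of the 10 largest falls (CDH1, EPCAM and CDA) lay in the lowest 30% of values, as did the pWZL level of ZEB2, so that these are not exact folds. Against shGFP in place of pWZL, 577 genes were higher and 641 lower, so that lower genes outnumbered higher ones, and CDH2 rose by 4.50.

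TGFb changed the fewest genes. TGFB1, the introduced ligand gene (203085_s_at), rose by 5.36 ± 0.08, although whether its probe set lies within the introduced sequence is not known here. FBN1, which encodes fibrillin, and POSTN rose by 5.57 ± 0.10 and 5.01 ± 0.09 (n = 3 against 3). COL1A1 rose by 4.10 ± 0.17, the cadherin gene CDH11 by 4.08 ± 0.14 and DCN by 3.93 ± 0.10. The cornified envelope gene SPRR1B fell by 4.90 ± 0.14, FGFR3 by 4.78 ± 0.16, the kallikrein gene KLK10 by 3.94 ± 0.12 and CDH1 by 2.57 ± 0.09, and EPCAM fell by 4.22 ± 0.12. ZEB1 rose by 3.51 ± 0.10, CDH2 by 3.33 ± 0.09 and VIM by 1.27 ± 0.06, and SNAI2 rose by 0.26 ± 0.06.

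Of 21 TGF-beta target genes, 17 rose and 0 fell with TGFb (17 and 0 adjusted over the list alone; median 0.61, adjusted p = 4.78e-12), including ID2 at 2.52 and IGFBP7 at 1.80. In shGFP against pWZL, 10 of these genes were higher and 3 lower (median 0.26, adjusted p = 0.0177, with an estimated correlation adjusted p = 0.083). Interferon-stimulated genes rose in 18 of 26 cases and fell in 2 (19 and 2 adjusted over the list alone; median 0.53, adjusted p = 6.02e-07), with IRF9 at 2.71, IFIT1 at 2.49 and ISG15 at 1.80. Junction genes fell in 18 of 24 cases and rose in 1 (19 and 1 adjusted over the list alone; median -0.81, adjusted p = 7.81e-11), and mesenchymal markers rose in 28 of 34 cases (29 adjusted over the list alone; median 0.97, adjusted p = 6.98e-23). At least 2-fold, 216 genes were higher and 182 lower (398 together), against 340 that differed between the controls, shGFP and pWZL. With no minimum fold 2790 genes changed with TGFb, and 3084 differed between the controls. Against shGFP in place of pWZL, 234 were higher and 441 lower (675 together), so that lower genes outnumbered higher ones. With that control KLK10 fell by 7.27, SNAI2 rose by 0.71 and ISG15 rose by 2.76, while IGFBP7 differed by 0.16 (adjusted p = 0.424). The highest adjusted p in the 20 genes with the largest rises and falls was 1.81e-13, and the pWZL levels of ID2 and of 2 of the 10 largest rises lay in the lowest 30% of values.

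The hairpin against E-cadherin lowered its target, CDH1, by 6.63 ± 0.09, from a log2 level of 12.74 ± 0.10 (SD, n = 3) in shGFP to 6.10 ± 0.04 (SD, n = 3) in shEcad. The elastic fibre gene FBLN5 rose by 8.53 ± 0.11, COL3A1 by 7.73 ± 0.12, COL1A2 by 7.45 ± 0.07, DCN by 7.06 ± 0.10 and CDH2 by 5.64 ± 0.09. The largest falls were those of KLK10, by 7.53 ± 0.12, SPRR1B by 7.41 ± 0.14, S100A8 by 7.21 ± 0.13, SLPI by 7.07 ± 0.10 and KLK7 by 6.94 ± 0.09, of which all but SLPI stand in the list of cornified envelope and squamous genes, and EPCAM fell by 6.32 ± 0.12. ZEB1 rose by 5.35 ± 0.10, TWIST1 by 3.12 ± 0.11 and VIM by 1.25 ± 0.06, while SNAI2 fell by 1.01 ± 0.06.

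Cornified envelope and squamous genes fell in 25 of 26 cases with shEcad (25 adjusted over the list alone; median -3.46, adjusted p = 1.55e-25), and these genes were also higher in shGFP than in pWZL by a median of 1.76. Inflammatory cytokines and chemokines fell in 20 of 24 cases and rose in 1 (20 and 1 adjusted over the list alone; median -2.37, adjusted p = 1.01e-14), among them IL1A, IL1B and CXCL1, which fell by 6.62, 5.02 and 4.08; their median was 0.97 higher in shGFP than in pWZL. Of 39 cell cycle genes, 21 rose and 4 fell (22 and 4 adjusted over the list alone; median 0.27, adjusted p = 0.013), with TYMS at 1.34 and BIRC5 at 1.26. Of 16 antigen presentation genes, 12 fell and 0 rose (13 and 0 adjusted over the list alone; median -0.59, adjusted p = 0.00011), including TAPBP and HLA-B, which fell by 1.44 and 1.05, and their median was 0.50 higher in shGFP than in pWZL. In all, 346 genes were at least 2-fold higher and 503 lower (849 together), and the highest adjusted p in the 20 genes with the largest rises and falls was 1.38e-17. The shGFP level of 3 of the 10 largest rises and the shEcad level of 2 of the 10 largest falls (KLK10 and SLPI) lay in the lowest 30% of values, as did the shGFP level of ZEB1. Against pWZL in place of shGFP, 380 genes were higher, 53.4% of those changed, so that higher genes outnumbered lower ones. With that control FBLN5 rose by 5.40, TWIST1 by 1.58, TYMS by 0.62 and BIRC5 by 0.50, and the differences were -4.21 for KLK10, -4.20 for S100A8, -3.96 for SLPI, -3.24 for KLK7, -2.51 for IL1B, -1.34 for CXCL1, -0.25 for HLA-B and -0.24 for TAPBP, whose change did not pass the test there (adjusted p = 0.269).

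**Figure D1:**
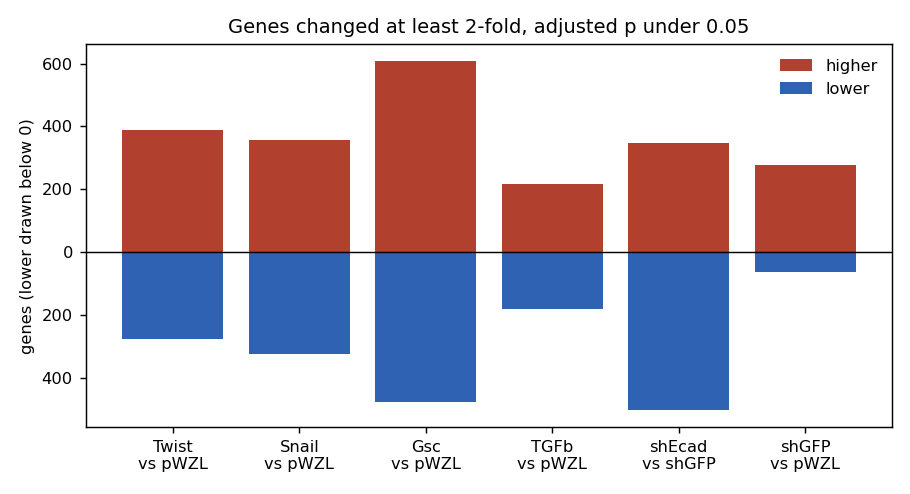
Numbers of genes at least 2-fold higher (bars above 0) and lower (bars below 0) at an adjusted p under 0.05, for the 5 comparisons and for shGFP against pWZL, with 3 arrays per group. Gsc had the tallest bar above 0, with 607 higher and 476 lower genes. shEcad had the tallest bar below 0, with 503 lower and 346 higher, and TGFb had 216 higher and 182 lower.

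**Figure D2:**
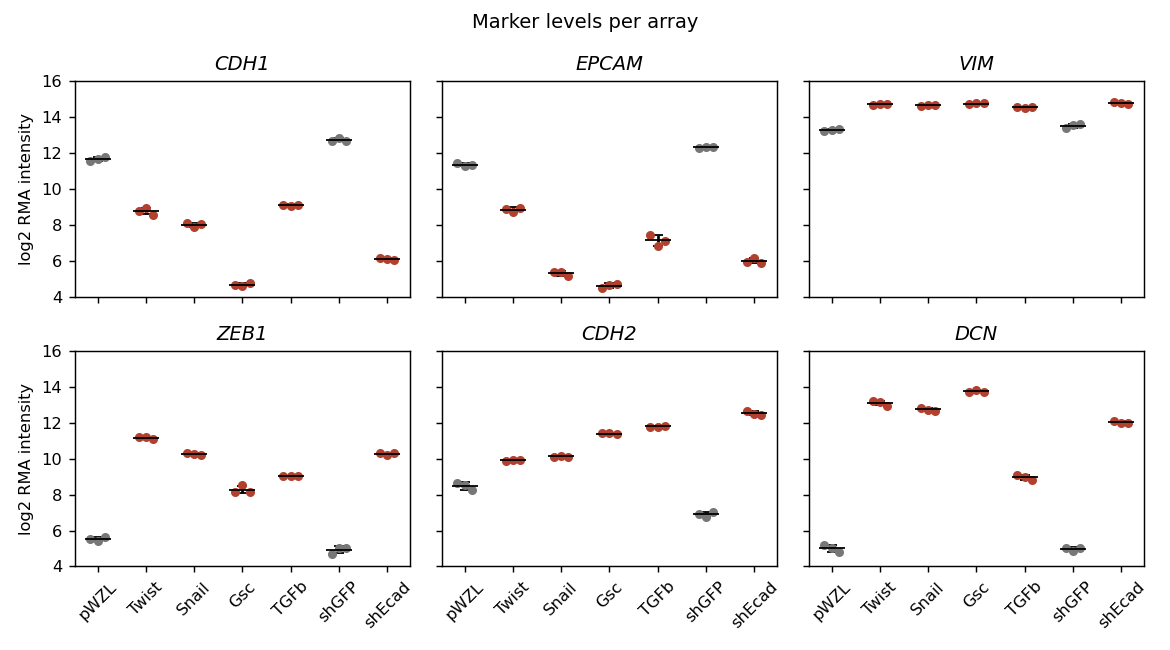
Log2 RMA intensity of CDH1, EPCAM, VIM, ZEB1, CDH2 and DCN on each of the 21 arrays by group, with a horizontal mark for the mean and a bar for the SD of 3 arrays; grey points are the control vectors. CDH1 was 12.74 in shGFP and 11.65 in pWZL, and lay lower in all 5 induced groups.

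The 5 comparisons shared 72 genes that were at least 2-fold higher and 108 that were at least 2-fold lower in each of them. With the other control vector these numbers were 82 and 166, of which 59 and 103 were among the 72 and 108. With both control vectors pooled they were 77 and 172, of which 61 and 105 were among them. The lower count thus depends on the control. So does membership of the higher set, which kept a smaller part of its genes. The shared genes with the largest smallest rise were FBN1, at least 5.57 in every comparison, POSTN, at least 5.01, and DCN, at least 3.93, followed by COL3A1, CDH11 and COL1A2. DCN read 4.82 to 5.21 on the pWZL arrays and 4.84 to 5.05 on the shGFP arrays. The lowest 30% of all values end at 5.20, so the size of the DCN rise depends on the background. ROR1, a receptor for the ligand encoded by WNT5A, was also among the shared higher genes, as were WNT5A and ZEB1. The shared lower genes were led by the growth factor receptor gene FGFR3, the kallikrein gene KLK10 and the protease inhibitor gene SLPI, and included CDH1, EPCAM, CXADR and IL18. VIM rose by 1.25 to 1.48 in the 5 comparisons from control levels of 13.27 and 13.52 to levels of 14.54 to 14.77, near the array maxima of 15.06 to 15.25, where folds can be compressed. The brightest probe set of FN1, the fibronectin gene (211719_x_at), was already at 14.17 in pWZL, also near the maxima, and rose by 0.25 to 0.76, whereas a dimmer one (214701_s_at) rose by 1.63 to 2.99. With the other control vector the brightest FN1 probe set rose by 0.19, 0.26, 0.34, 0.20 and 0.66 with Twist, Snail, Gsc, TGFb and shEcad.

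Keratins fell in all 5 comparisons. Of 9 measured, 8 fell with Twist, 8 with Snail, 7 with Gsc, 7 with TGFb and 8 with shEcad, the same numbers as adjusted over the list alone, and the adjusted p was at most 4.62e-06. In shGFP against pWZL, 7 keratins were higher and 0 lower (median 0.52). Fibroblast markers rose in 11, 11, 9, 9 and 10 of 11 cases in the same order, again the same numbers as adjusted over the list alone, with medians of 4.20, 2.71, 3.92, 1.76 and 2.09; 10 of these 11 genes also stand in the mesenchymal or collagen list. FAP, a membrane protease gene among them, fell by 2.16 ± 0.10 with Gsc, the only fall, and fell by 3.34 with shGFP in place of pWZL. Markers of endothelial cells, leukocytes and adipocytes were not called in any of the 5 comparisons. CD44, a surface marker, was not uniform: the brightest probe set (212063_at) rose by 0.26 with Twist, 0.49 with Gsc and 0.48 with TGFb and fell by 0.62 with shEcad, each ± 0.09, while its difference with Snail, 0.23 ± 0.09, did not pass the test. Another probe set of CD44 (209835_x_at) fell by 1.11 with Gsc and by 0.42 with TGFb. With shGFP in place of pWZL the brightest probe set fell by 0.71, 0.48 and 0.49 with Twist, Gsc and TGFb, and with pWZL in place of shGFP it rose by 0.35 with shEcad.

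Lists of these sizes would share 0.00108 higher and 0.000674 lower genes if they were independent, which 4 comparisons with the same pWZL arrays are not. In simulated unchanged groups the largest count of genes changed in a comparison was 0. Their overlap of 0 was thereby fixed in advance and says nothing of what a shared control adds. Across genes, which are not independent replicates, fold changes of Twist and Snail correlated with r = 0.878 (covariance 0.441). The simulated r, from the spread among arrays with pWZL shared, was 0.513 (covariance 0.00574). The correlations of the 4 pWZL comparisons with shEcad, which has its own control arrays, ran from 0.595 for Gsc to 0.753 for Snail, with covariances of 0.260 to 0.462 and simulated covariances of -0.0001 to 9.62e-05. Among the pWZL comparisons, Gsc and TGFb had the lowest r, 0.564 against a simulated 0.515, with a covariance of 0.255 against 0.00572. The simulated groups hold no effects, so their r is not the part of the real r that shared arrays bring. The simulated covariances measure only what the spread among the arrays of a group brings. They were small beside the real ones. A deviation of the pWZL cultures themselves would enter all 4 pWZL comparisons. It is not in the simulation, so its part was not measured. The control vectors differed from each other in 340 genes at least 2-fold. The 3 pWZL arrays were too few to give each of those 4 comparisons controls of its own.

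The control vectors differed from each other. SPRR2B, a cornified envelope gene, was higher in shGFP than in pWZL by 5.19 ± 0.08, the stromelysin gene MMP10 by 4.60 ± 0.08 and the decoy receptor gene IL1R2 by 4.28 ± 0.13 (n = 3 against 3). CUX2, FBLN5 and NEDD9 were lower, at -3.32 ± 0.15, -3.13 ± 0.11 and -3.03 ± 0.08. The pWZL level of MMP10 and the shGFP level of CUX2 lay in the lowest 30% of values. Cornified envelope and squamous genes were higher in 23 of 26 cases (median 1.76, adjusted p = 2.98e-20) and junction genes in 18 of 24 (median 0.66, adjusted p = 1.06e-08), whereas of 34 mesenchymal markers 8 were higher and 9 lower (median -0.08, adjusted p = 0.367). In all, 276 genes were at least 2-fold higher and 64 lower in shGFP (340 together). Among the 3 largest differences in either direction, the highest limma adjusted p was 8.22e-13, although both groups are controls.

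Set against each other directly, Twist and Snail differed least, in 215 genes, and Gsc and TGFb most, in 799. LUM was higher with Twist than with Snail by 5.85 ± 0.14 and COL5A1 was lower, at -3.26 ± 0.12. Twist and Gsc differed in 627 genes and Snail and Gsc in 570. SCG2 was lower with Twist than with Gsc, at -6.41 ± 0.11, as were PTN, a neurite growth factor gene, at -5.95 ± 0.12 and the neuronal adhesion gene NRCAM at -5.81 ± 0.24. TGFBI was higher with Snail than with Gsc by 6.58 ± 0.14. Twist and TGFb differed in 436 genes and Snail and TGFb in 439; the syndecan gene SDC2 was higher with Twist than with TGFb by 6.85 ± 0.10 and with Snail than with TGFb by 6.13 ± 0.10. MGP was higher with Gsc than with TGFb by 7.47 ± 0.16 and TGFBI was lower, at -7.12 ± 0.14. The highest adjusted p among the 3 largest differences in either direction of any of these 6 contrasts was 1.82e-13.

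The effect of each overexpression was also set against that of the E-cadherin hairpin, each relative to its own control. The change in CDH2 was smaller with Twist than with shEcad, by a difference of -4.19 ± 0.12, and with Snail, by -3.98 ± 0.12. MMP1, a collagenase gene, differed by 6.13 ± 0.19 between Snail and shEcad. MGP and LUM rose more with Gsc than with shEcad, by 7.21 ± 0.22 and 6.76 ± 0.20, whereas TGFBI differed by -6.56 ± 0.20. The chemokine gene CXCL1 differed by 5.45 ± 0.14 between TGFb and shEcad, and ANPEP by -5.43 ± 0.14. Such differences reached at least 2-fold in 605 genes for Twist, 562 for Snail, 1073 for Gsc and 802 for TGFb. These values contain the difference between the control vectors, which in shGFP against pWZL was 3.01 ± 0.13 for MMP1, 2.73 ± 0.10 for CXCL1 and -1.58 ± 0.09 for CDH2. It also enters the differences of MMP10 and IL1R2 for Twist, 5.31 ± 0.12 and 5.27 ± 0.18, and of FBLN5 for Gsc, -5.46 ± 0.16.

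Some genes rose in a comparison and fell in another. At least 2-fold changes in opposite directions were found for 60 genes, each comparison with its own control. This count was not repeated with a common control. The neuronal adhesion gene NRCAM rose by 4.09 ± 0.24 with Gsc and fell by 3.64 ± 0.24 with shEcad, and EREG, which encodes a ligand of the EGF receptor, rose by 1.86 ± 0.13 with Gsc and fell by 4.13 ± 0.13 with shEcad. The potassium channel gene KCNJ15 rose by 1.49 ± 0.09 with TGFb and fell by 4.36 ± 0.09 with Gsc. IGFBP2, an insulin-like growth factor binding protein gene, rose by 3.15 ± 0.08 with Gsc and fell by 2.65 ± 0.08 with TGFb. NRCAM and EREG were also higher in shGFP than in pWZL, by 2.15 ± 0.24 and 0.80 ± 0.13, which enters their contrast between Gsc and shEcad.

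**Figure D3:**
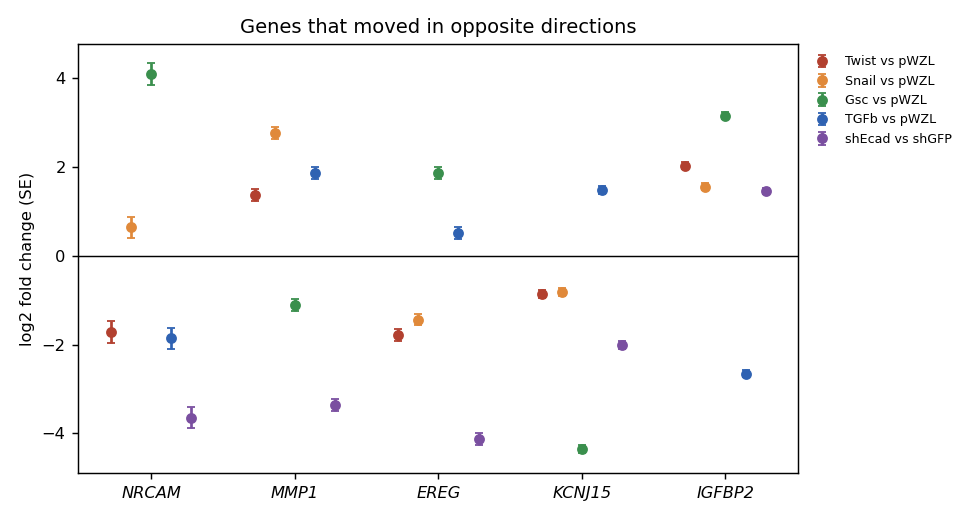
Log2 fold change (points) with its SE (bars) of the 5 genes with the largest differences among those changed at least 2-fold in opposite directions, in the 5 comparisons (colours), with 3 arrays per group. NRCAM ran from -3.64 with shEcad to 4.09 with Gsc.

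**Figure D4:**
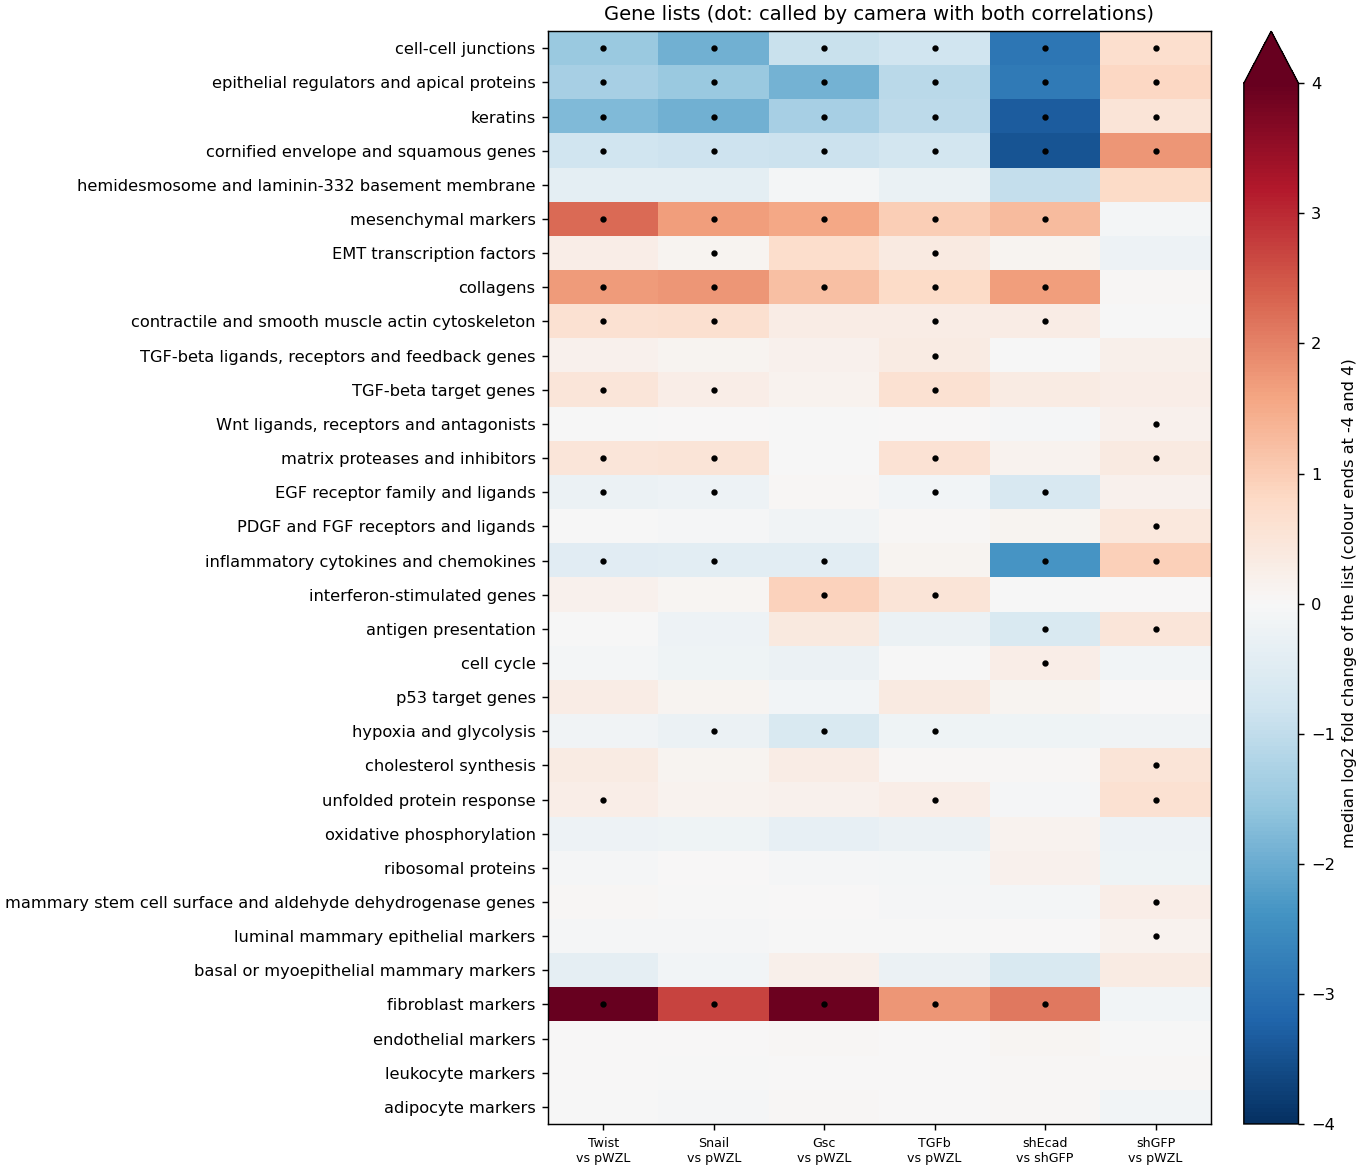
Median log2 fold change of the 32 gene lists (top to bottom) in the 5 comparisons and in shGFP against pWZL (left to right), as colour from blue (lower) to red (higher), with a dot where the camera test passed with the preset and with the estimated correlation. Junction genes, epithelial regulators, keratins and cornified envelope genes lay below 0 in all 5 comparisons, and mesenchymal, collagen and fibroblast lists lay above 0.

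Of 160 list tests, 81 passed with the preset correlation and 65 of those passed in the same direction with an estimated correlation. The calls named for the single comparisons, keratins and fibroblast markers held with the estimated correlation. The list tests of shGFP against pWZL and of Twist against Snail were chosen after the values were seen. Median, mean and test differed in sign in 28 of the 160 tests, of which 0 were called with the preset correlation. The deposited values are processed intensities without detection calls, so that low levels carry no bound of their own.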

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

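The mixture and batch tests in this part, the 5 gene differences singled out and the count of probe sets without a single gene were chosen after the results were seen.

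Over the 72 higher and 108 lower genes shared by all 5 comparisons, TGFb had the smallest medians, 1.90 and -1.65, against 2.75 to 3.11 and -2.11 to -3.31 for the others. A mixture of pWZL-like cells with cells in the state of the other groups may be proposed, but on the linear scale, over the 140 higher and 167 lower genes shared by the other 4 comparisons, the genes that rose implied a share of 0.220 of such cells and the genes that fell a share of 0.801, a difference of -0.581 (95% bootstrap interval -0.66 to -0.509), where a mixture needs equal shares. A mixture with those end states as the whole cause is thereby argued against, while a weaker or partial response of all cells stays open and was not tested. The interval resampled genes, which are not independent replicates.

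The shGFP arrays lay further than the pWZL arrays from the induced groups on the shared lower genes: of 108 such genes, 74 were higher and 8 lower in shGFP (median 0.86), whereas of 72 shared higher genes 22 were higher and 26 lower (median -0.07). A share of induced-like cells in the pWZL cultures may be proposed, which needs equal shares from both sets of genes. The genes that rose implied a share of 0.003 and the genes that fell a share of 0.496. The difference was -0.493 (95% bootstrap interval -0.561 to -0.37, resampling genes, which are not independent replicates). These genes were chosen for changes of at least 2-fold from pWZL. That choice caps the share from genes that rose more tightly than that from genes that fell, so the difference does not decide on such a mixture. An effect of the vectors or hairpin and a difference between culture or array batches cannot be told apart, because 0 labels give a batch or date.

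The effects of Twist, Snail, Gsc and TGFb differed from that of the E-cadherin hairpin, by the test of the difference, in 605, 562, 1073 and 802 genes. Of 100 random assignments of the 12 arrays to 4 groups, the real one included, 6 gave as many genes for Twist (highest other 1598), 6 for Snail (highest other 1664), 3 for Gsc (highest other 1826) and 4 for TGFb (highest other 1337). A first run of 25 assignments had given 1, 2, 2 and 1 in the same order (highest other 573, 762, 1204 and 437), and the number was then raised to 100. The assignments do not keep the differences between the 4 groups, a structure of the samples that enters their counts by construction, so these numbers neither exclude chance nor speak for it.

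The direct contrasts differed between groups in 215 genes for Twist and Snail, 627 for Twist and Gsc, 436 for Twist and TGFb, 570 for Snail and Gsc, 439 for Snail and TGFb and 799 for Gsc and TGFb. In these 6 contrasts and in the 5 comparisons with a control (668, 683, 1083, 398 and 849 genes for Twist, Snail, Gsc, TGFb and shEcad) the highest count of the other splits of the 6 arrays was 0, and for shGFP against pWZL (340 genes) it was 4. The real split was the only 1 of 10 with so many genes in each case, and 10 splits are too few for a share under 0.05. For the genes shared by all 5 comparisons, 72 higher and 108 lower, 1 of 100 random assignments of the 21 arrays, the real one, gave as many (highest other 0). These assignments, too, mix the groups, whose differences then widen the spread within groups, so they neither exclude chance nor speak for it.

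In 60 genes, 2 comparisons differed in direction at 2-fold or more. With pWZL as the control of the overexpressions and shGFP as that of the hairpin, the largest differences were those of NRCAM between Gsc and shEcad (7.73), MMP1 between Snail and shEcad (6.13), EREG between Gsc and shEcad (5.99), KCNJ15 between TGFb and Gsc (5.85) and IGFBP2 between Gsc and TGFb (5.81). The first 3 contain the difference of shGFP from pWZL, 2.15 for NRCAM, 3.01 for MMP1 and 0.80 for EREG, and the order depends on it. With a common control MMP1 was no longer opposed at 2-fold between Snail and shEcad. Its values were 2.76 and -0.36 against pWZL, and -0.25 (adjusted p = 0.148) and -3.37 against shGFP. Against shGFP, NRCAM (1.94 and -3.64) and EREG (1.06 and -4.13) stayed opposed between Gsc and shEcad. The count of 60 was not repeated with a common control. Among 1841 probe sets with several gene symbols or none, which the comparisons did not use, 5 were at least 2-fold higher and 26 at least 2-fold lower in all 5 comparisons.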

How the results depend on the processing

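A second quantile normalization, centring on medians, leaving out the dimmest genes, means of probe sets, leaving out _x_at probe sets, separate fits, array weights, another prior and an adjusted p under 0.01 kept every count of changed or shared genes within 1.5 times. The split into higher and lower genes was less stable. Centring on medians gave 341 higher and 343 lower genes for Snail, against 358 and 325 without it. In the other comparisons with a control the larger direction stayed the same. For shGFP against pWZL 293 genes differed after centring and 295 after the second quantile normalization, against 340. Leaving out each array in turn moved these counts by at most 1.14 times, the most for shGFP against pWZL (323 to 386). The replicate numbers paired the arrays weakly if at all, and no test of pairing was run. The median correlation was 0.022 for same-number pairs, of which 15 of 63 lay above 0.1, and -0.009 for different numbers. Of 21 arrays, 10 had their highest mean correlation with their own number. With the number as a block 668 genes changed with Twist. The number of arrays and the background of dim probe sets limit what small changes can show.

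With a minimum of 1.5-fold, which admits smaller changes, 1382, 1481, 2170, 1028 and 1744 genes changed with Twist, Snail, Gsc, TGFb and shEcad, and 1151 differed between the controls. The direct contrasts then gave 509 for Twist and Snail, 1364 for Twist and Gsc, 1069 for Twist and TGFb, 1282 for Snail and Gsc, 1071 for Snail and TGFb and 1736 for Gsc and TGFb. The differences from the hairpin effect were 1486, 1419, 2263 and 1738, and 164 higher and 210 lower genes were shared. With no minimum fold the same counts, in the same order, were 3268, 3391, 4097, 2790 and 3771 genes, 3084 between the controls, 1480, 3213, 2856, 3079, 2845 and 3606 in the direct contrasts, 2784, 2601, 3547 and 2957 against the hairpin, and 411 and 462 shared.

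With the other control vector 418 genes were higher and 528 lower for Twist, 406 and 559 for Snail, 577 and 641 for Gsc, 234 and 441 for TGFb (675 together) and 380 higher (53.4% of those changed) for shEcad, against 390 and 278, 358 and 325, 607 and 476, 216 and 182, and 346 and 503 with the chosen controls. Then 82 higher and 166 lower genes were shared, of which 59 and 103 were among the 72 and 108 with the chosen controls. With both pooled these numbers were 77 and 172 shared, of which 61 and 105 were among them. Directions turned with the other control for CD44 (-0.71 Twist, -0.48 Gsc, -0.49 TGFb, 0.35 shEcad), CXCL1 (-2.06 Twist, -1.35 TGFb), MMP1 (-1.64 Twist, -1.14 TGFb), MMP10 (-4.11 Twist, -4.32 Snail), NEDD9 (1.35 Twist, 0.61 Snail, 0.83 Gsc, 2.62 TGFb, -2.10 shEcad), SNAI2 (0.28 Twist), NRCAM (-1.51 Snail), TAPBP (-0.54 Gsc), CUX2 (0.55 TGFb) and MPPE1 (-0.38 TGFb). With both pooled they turned for CD44 (-0.23 Twist), CXCL1 (-0.70 Twist), MMP10 (-1.81 Twist, -2.02 Snail) and NEDD9 (1.11 TGFb, -0.59 shEcad). The difference between the controls enters these values by construction.

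With means of probe sets, directions turned for CD44 (-0.56 Gsc, -0.18 TGFb), MPPE1 (-0.23 Snail, -0.33 TGFb) and DST (-0.83 shEcad), and without _x_at probe sets for MPPE1 (-1.07 Twist, -1.19 Snail, -1.49 Gsc, -1.16 TGFb) and PTN (-0.27 shEcad), where another probe set stands for the gene. Leaving TGFb out of the intersection gave 140 higher and 167 lower shared genes. Fry, which tests a list without comparing it with other genes, called 143 of 160 list tests.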

Other observations

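The tests of list differences between groups and of lists between the control vectors in this part were chosen after the values were seen. Contractile and smooth muscle actin genes rose in 13 of 17 cases with Twist and fell in 0 (14 and 1 adjusted over the list alone; median 0.62, camera adjusted p = 6.38e-07). They rose in 12 and fell in 1 with Snail (12 and 1 adjusted over the list alone; adjusted p = 1.26e-05), rose in 8 and fell in 0 with TGFb (9 and 0 adjusted over the list alone; adjusted p = 0.000101) and rose in 10 and fell in 1 with shEcad (10 and 1 adjusted over the list alone; adjusted p = 0.000626), and the list was not called with Gsc (adjusted p = 0.0686). Matrix proteases and their inhibitors rose in 17 of 29 cases and fell in 2 with Twist, rose in 17 and fell in 3 with Snail, and rose in 18 and fell in 2 with TGFb (17 and 2, 17 and 3, and 19 and 2 adjusted over the list alone), with medians of 0.49, 0.52 and 0.57 (adjusted p = 3.39e-07, 1.76e-05 and 1.9e-07). These proteases were not called with Gsc or shEcad (adjusted p = 0.137 and 0.914), and in shGFP against pWZL 17 were higher and 2 lower (median 0.37). EGF receptor family genes and ligands fell in 7 of 15 cases and rose in 4 with Twist, fell in 7 and rose in 3 with Snail, fell in 6 and rose in 2 with TGFb, and fell in 8 and rose in 1 with shEcad (8 and 4, 8 and 3, 7 and 2, and 8 and 1 adjusted over the list alone; adjusted p = 0.0112, 0.0169, 0.0129 and 1.75e-05). They were not called with Gsc (adjusted p = 0.416), and in shGFP against pWZL 6 were higher and 0 lower (median 0.19). Inflammatory cytokines fell in 14, 13 and 14 of 24 cases and rose in 3, 2 and 1 with Twist, Snail and Gsc (14, 14 and 15 falls adjusted over the list alone; adjusted p = 0.000285, 0.000167 and 0.000259), and were not called with TGFb (adjusted p = 0.894); in shGFP against pWZL 18 were higher and 1 lower (median 0.97).

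EMT transcription factors rose in 6 of 13 cases and fell in 2 with Snail, and rose in 9 and fell in 1 with TGFb (6 and 2, and 9 and 1 adjusted over the list alone; adjusted p = 0.0257 and 0.000286). With Gsc they rose in 8 cases and fell in 4 (8 and 4 adjusted over the list alone; adjusted p = 0.0485), a call lost with an estimated correlation (adjusted p = 0.0733), and they were not called with Twist or shEcad (adjusted p = 0.146 and 0.306). TGF-beta target genes rose in 12 of 21 cases and fell in 5 with Twist, and rose in 11 and fell in 4 with Snail (13 and 5, and 13 and 4 adjusted over the list alone; adjusted p = 0.00011 and 9.92e-05). They rose in 11 and fell in 4 with shEcad (12 and 4 adjusted over the list alone; adjusted p = 0.0169), where the call was lost with an estimated correlation (adjusted p = 0.0977), and with Gsc the adjusted p was 0.191. TGF-beta ligands, receptors and feedback genes were called with TGFb, where 12 of 25 rose and 1 fell (14 and 1 adjusted over the list alone, median 0.34, camera adjusted p = 0.000207). TGFB1, the introduced gene, is a member of this list and enters its count and test, and the list was not tested without it. In shGFP against pWZL 11 genes of the list were higher and 2 lower (median 0.21). Genes of the unfolded protein response rose in 9 of 14 cases and fell in 1 with Twist, and rose in 8 and fell in 0 with TGFb (9 and 1, and 9 and 1 adjusted over the list alone; medians 0.26 and 0.26, adjusted p = 0.0105 and 0.000486). In shGFP against pWZL, 10 of these genes were higher and 3 lower, with a larger median of 0.61 (adjusted p = 0.00123). Hypoxia and glycolysis genes fell in 12 of 23 cases and rose in 4 with Snail, and fell in 8 and rose in 3 with TGFb (14 and 4, and 10 and 3 adjusted over the list alone; adjusted p = 0.0331 and 0.0118).

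Oxidative phosphorylation genes fell in 18, 14, 21 and 16 of 29 cases and rose in 2, 2, 0 and 1 with Twist, Snail, Gsc and TGFb (20, 15, 22 and 17 falls adjusted over the list alone; medians -0.22, -0.18, -0.32 and -0.22, adjusted p = 0.00437, 0.0143, 9.07e-05 and 0.000285). These calls were lost with an estimated correlation (adjusted p = 0.235, 0.307, 0.107 and 0.138), and in shGFP, too, 16 were lower than in pWZL and 2 higher (median -0.20, adjusted p = 3.45e-05, with an estimated correlation adjusted p = 0.0737). Of 13 p53 target genes, 8 rose and 2 fell with Twist, and 7 rose and 0 fell with TGFb (8 and 2, and 7 and 0 adjusted over the list alone; adjusted p = 0.022 and 0.00754, with an estimated correlation adjusted p = 0.157 and 0.0986). Of 17 cholesterol synthesis genes, 10 rose and 2 fell with Twist and the same numbers with Gsc (10 and 2 adjusted over the list alone in both; medians 0.32 and 0.29, adjusted p = 0.0105 and 0.0195, with an estimated correlation adjusted p = 0.0921 and 0.122). In shGFP against pWZL, 12 of these genes were higher and 1 lower, with a larger median of 0.52 (adjusted p = 2.05e-06). Antigen presentation genes rose in 9 of 16 cases and fell in 1 with Gsc, and fell in 6 and rose in 1 with TGFb (9 and 1, and 7 and 1 adjusted over the list alone; adjusted p = 0.0264 and 0.0209, with an estimated correlation adjusted p = 0.078 and 0.0687); in shGFP against pWZL 11 were higher and 0 lower (median 0.50).

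With shEcad, 15 of 30 ribosomal protein genes rose and 0 fell (17 and 0 adjusted over the list alone; median 0.17, adjusted p = 0.00365, with an estimated correlation adjusted p = 0.27), and 18 of them were lower and 0 higher in shGFP than in pWZL (median -0.17, adjusted p = 2.91e-06, with an estimated correlation adjusted p = 0.0684). Of 9 hemidesmosome and laminin genes, 7 fell and 1 rose (7 and 1 adjusted over the list alone; median -0.96, adjusted p = 0.000589, with an estimated correlation adjusted p = 0.103), and 8 were higher and 0 lower in shGFP than in pWZL (median 0.75). The 1 rise was that of DST by its brightest probe set (0.69), whereas another of its probe sets (204455_at) fell by 4.27. Of 12 basal markers, 8 fell and 3 rose (8 and 3 adjusted over the list alone; median -0.61, adjusted p = 0.0108, with an estimated correlation adjusted p = 0.0722), and 8 were higher and 2 lower in shGFP than in pWZL (median 0.34). Of 14 mammary stem cell genes, 6 fell and 2 rose (6 and 2 adjusted over the list alone; median -0.07, adjusted p = 0.0297, with an estimated correlation adjusted p = 0.0514), and 8 were higher and 1 lower in shGFP than in pWZL (median 0.27). Wnt genes, PDGF and FGF genes and luminal markers were not called in any of the 5 comparisons, with lowest adjusted p values of 0.0838, 0.3 and 0.0926, and markers of endothelial cells, leukocytes and adipocytes had lowest adjusted p values of 0.683, 0.703 and 0.24.

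Interferon-stimulated genes changed more with Gsc than with shEcad, with 20 of 26 higher and 0 lower in the test of the difference (median 1.08, adjusted p = 6.89e-10, with an estimated correlation adjusted p = 0.0159). For TGFb against shEcad the adjusted p was 2.24e-05, and with an estimated correlation adjusted p = 0.0734.

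Probe sets of DST, a gene of the hemidesmosome list, moved apart. The probe set 212254_s_at rose by 1.64 with Twist, 1.19 with Snail and 2.36 with Gsc, and 204455_at fell by 1.84, fell by 2.46 and fell by 2.16 in the same comparisons. Of 3505 genes with more than 1 probe set, 2 had probe sets changed at least 2-fold in opposite directions within a comparison, DST and MPPE1, which were chosen after their values were seen.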
